A study of Homo sapiens with 16 samples.

How the data were processed

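Total RNA from sucrose gradient fractions of 293S cells was sequenced after Trizol extraction and a priming method named NSR, per the labels' protocols. The cells were untreated or had received 1 mM sodium arsenite for 30 minutes. Each gradient had 8 fractions and each fraction 1 library, so the 16 libraries form 16 groups of 1. Groups were taken from the sample titles.

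The authors deposited 1 table of 13148 genes. Its values in the 16 library columns are in the unit fraction, that is, the share of a gene's total that lay in a given fraction of the gradient, and the 8 deposited values of a gene in a gradient summed to 1 within 2.3e-15. Per the file headers, the values refer to exons of RefSeq genes. The genome build was hg19, per the submitters' processing notes. The aligner, the counting method, the treatment of strand, the gene filter, and the scaling of the fractions against each other are not given in the sources used here. The authors also deposited 3 score columns, the mean fraction number of each gene in each gradient and their difference. The mean fraction number was recomputed from the shares and differed from the deposited score by at most 1.5e-14. All columns were used. Shares carry no expression level, and the depth of each library is unknown, so no interval or detection floor is given. A share of exactly 0 is reported as listed at 0. There were 1523 genes with a 0 in at least 1 library and 11625 with none.

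Position was the sum of fraction number times share. The shift was position with arsenite minus position in the control, and the relative shift was the shift minus its median over all genes. A gene was called moved when its relative shift was at least 0.5 fractions in size and kept its sign when each fraction number was left out of both gradients in turn; 240 genes of that size changed sign and were not called. The share in fractions 5 to 8 served as a second summary. Matched fractions were compared as log2 ratios of shares in percent after adding a pseudocount of 1 percentage point. The median relative shift of each fixed gene list was set against 10000 random lists of the same size drawn with replacement from all genes, and a list was said to stand apart when its median lay outside their central 95%. This describes these libraries and is not a test between conditions.

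The lists, the rules and most alternatives were fixed before the data were examined. They assumed values that keep an expression level, and some parts could not be applied to shares. The summed abundance of a transcript over the 8 fractions, filters on low values and random lists matched on expression were not computed, because every gene has a mean share of 12.5% in each gradient. The table has 1 row per gene, so no choice between rows arose. The rule for named genes took the 10 moved genes with the largest relative shift in each direction, the member of each list with the largest relative shift, and 12 single genes chosen in advance, of which 11 were in the table. The parts of the rule that needed an expression level (the 2 members of each list with the highest mean value, and genes that changed in summed abundance) could not be applied. Other members of the fixed lists were named as examples after their values were seen. The lists of mitochondrially encoded mRNAs and of nuclear and structural noncoding RNAs had no member in the table.

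Alternatives were median-of-ratios size factors over the 16 libraries, a pseudocount of 1 percentage point before shares were taken, pseudocounts of 0.1 and 10 on the log scale, leaving out each fraction, thresholds of 0.25 and 1 fractions, the point at which 50% of the total is reached, and the share in fractions 5 to 8 for the lists. Those added after the data were seen were the use of genes with no 0, and random lists matched on control position (20 bins), on mRNA length (10 bins), or on control position (5 bins) and mRNA length (10 bins).

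For lengths, untranslated regions and sequence, 1 protein-coding transcript per gene was taken from GENCODE release 29 by gene symbol. It was the principal isoform unless its coding part was under 50% of the longest of the gene, in which case the longest coding part was used. Symbols matched for 13030 genes (99.1%), of which 720 were found by an older symbol. That annotation is on another build than hg19, so no coordinates are given.

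The calls were tested on simulated profiles of 11904 genes for the comparison of arsenite with control, with a common shift of −1.4 fractions and 100 genes planted at 1 fraction in each direction. At an assumed 100 reads per gene and gradient, 99% of the genes planted higher and 97% of those planted lower were recovered, and 3.09% of the other genes were called moved. At 1000 reads the values were 100%, 99% and 0.02%. The common shift was set after the data were examined, and the simulation was run with 2 values of it, of which the second is given. Of 500 lists of 25 unplanted genes, 3.4% stood apart at 100 reads and 4.8% at 1000. These lists were random draws set against random draws of the same values, so a low rate follows by construction. Unplanted genes shared 1 common shift, so lists of genes alike in length or control position were not covered. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.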

Results

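Human 293S cells, an established line of the HEK293 family, were left untreated or exposed to 1 mM sodium arsenite for 30 minutes. Arsenite reacts with thiol groups, causes oxidative stress and is widely used to set off the cellular stress response. RNA from each treatment was spread over a sucrose gradient, which sorts RNA by the size of the particles it travels with, such as mRNAs carrying ribosomes. Each gradient was sequenced as 8 fractions, giving 16 libraries with 1 library for each treatment and fraction. There was no replicate, so no difference below has a replicate check and no p-value is given. For each of 13148 genes the deposited values were its shares over the 8 fractions of a gradient, which add up to 1, so neither the level of a transcript nor the read depth behind a share is known. The position of an mRNA is its mean fraction number, weighted by these shares. The series as a whole concerns contacts between Argonaute 2 and mRNAs under stress and their relation to translation. The gradients ask where each mRNA lay with and without arsenite.

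In untreated cells, mRNAs were spread widely, and the median position was 4.54 with quartiles over genes of 4.14 and 4.96. Fraction 5 was the largest fraction for 28.6% of genes, fraction 6 for 21.6% and fraction 4 for 20.6%. The labels do not say which end of the gradient was fraction 1. The mRNAs of 75 cytosolic ribosomal proteins, which have short coding sequences, had a median position of 3.91, and 39 mRNAs with very long coding sequences had one of 5.29. Glycolytic enzyme mRNAs lay furthest along of the fixed lists, at 5.74 over 16 genes. ACTB, which encodes cytoplasmic beta-actin, had 46.3% of its total in fraction 6. HSPA5, the main chaperone of the endoplasmic reticulum, had 80.9% of its total in fractions 5 to 8. ATF4, a transcription factor of the integrated stress response, lay lower, at 3.67, with 21.6% in fractions 5 to 8.

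With arsenite, nearly all mRNAs lay at lower fraction numbers. The median position was 3.10, with quartiles of 2.66 and 3.50, and the median shift was −1.46 fractions, with quartiles of −1.97 and −0.98. The shift was negative for 12920 genes (98.3%) and positive for 228, of which 55 had no value of 0 in any library. The median share in fractions 5 to 8 was 53.9% in the control and 16.4% with arsenite, and it was lower with arsenite for 12585 genes (95.7%). At least 50% of the total lay in these fractions for 7711 genes in the control and for 308 with arsenite. ACTB lay at 5.40 in the control and at 2.37 with arsenite, GAPDH at 4.88 and 2.19, and TUBB, a beta-tubulin, at 5.84 and 2.92. MYC lay at 5.20 and 3.13. HSPA5 lay at 6.03 and 4.24 and kept 52.4% of its total in fractions 5 to 8. The size of the common shift depended on how the fractions were weighted against each other, which is not given in the sources used here. With median-of-ratios size factors, which make the typical gene alike in every library by construction, the median shift was −0.23, so genes and lists are compared below by their shift relative to the median gene.

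**Figure D1:**
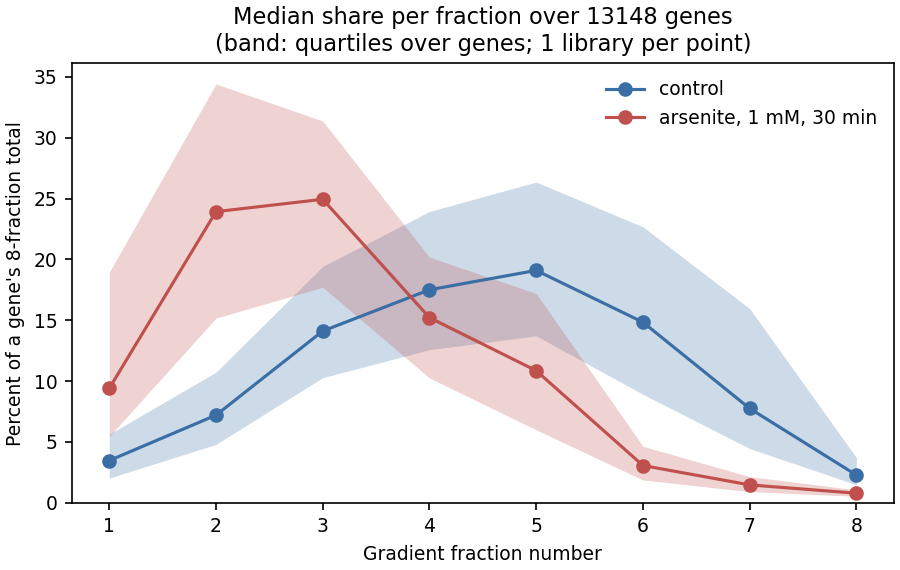
Median share of a gene's 8-fraction total (y axis, percent) against gradient fraction number (x axis) over 13148 genes in untreated and arsenite-treated 293S cells. Points are medians from 1 library each and bands span the quartiles over genes. The control median is highest in fraction 5 at 19.1% and the arsenite median in fraction 3 at 24.9%.

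Compared fraction by fraction, the change was largest in fraction 2, where the median log2 ratio of arsenite to control was 1.50, and in fractions 6 and 7, where it was −1.85 and −1.86. These values are on the log2 scale after adding 1 percentage point to each share, which understates the change of small shares. Fractions 2 and 3 were the largest fraction for 34.5% and 37.2% of genes with arsenite. Across genes, which are not independent replicates, the Spearman correlation of the matched libraries was 0.60 in fraction 1, −0.28 in fraction 5 and 0.45 in fraction 7. Arsenite fraction 3 listed 728 genes at 0, against 178 in fraction 2 and 155 in fraction 4 of the same gradient. The direction of the medians of fractions 2, 3, 5 and 6 was the opposite with size factors.

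Against the median gene, 3101 genes moved to higher fraction numbers and 3159 to lower ones, by at least 0.5 fractions and with the same sign when each fraction was left out of both gradients in turn. The remaining 6888 did not meet this rule. Across genes the shift had a Spearman correlation of −0.55 with the control position, which is itself part of the shift. Genes that started at low numbers thus tended to have higher relative shifts, and the calls of single genes are not corrected for this. With size factors relative shifts were in general more spread out, with quartiles of −0.74 and 0.63 against −0.52 and 0.48, and relative shifts of genes and lists given below that differed by at least 1.5 times are printed with that value. ATF4 was among those that moved higher, and in the deposited shares it lay at 3.67 in the control and 3.79 with arsenite (relative shift 1.57). PPP1R15A, which encodes the stress-induced regulatory subunit of the phosphatase that acts on eIF2 alpha, lay at 4.39 and 4.03 (1.10). EIF2C2, which encodes Argonaute 2, lay at 4.65 and 3.86 (0.67). At the other end, ENO1, a glycolytic enzyme, lay at 5.94 in the control and 2.41 with arsenite (−2.07), the alpha-tubulin gene TUBA1A at 5.86 and 2.26 (−2.14), and NUP37, a nuclear pore subunit, at 5.66 and 1.91 (−2.30). EEF1A1, the translation elongation factor, had a relative shift of 0.40 (0.14 with size factors) and did not meet the rule, though without fraction 7 it did, at 0.98. MYC had a relative shift of −0.61 and met the rule, but without fraction 7 it lay at −0.31 and did not.

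**Figure D2:**
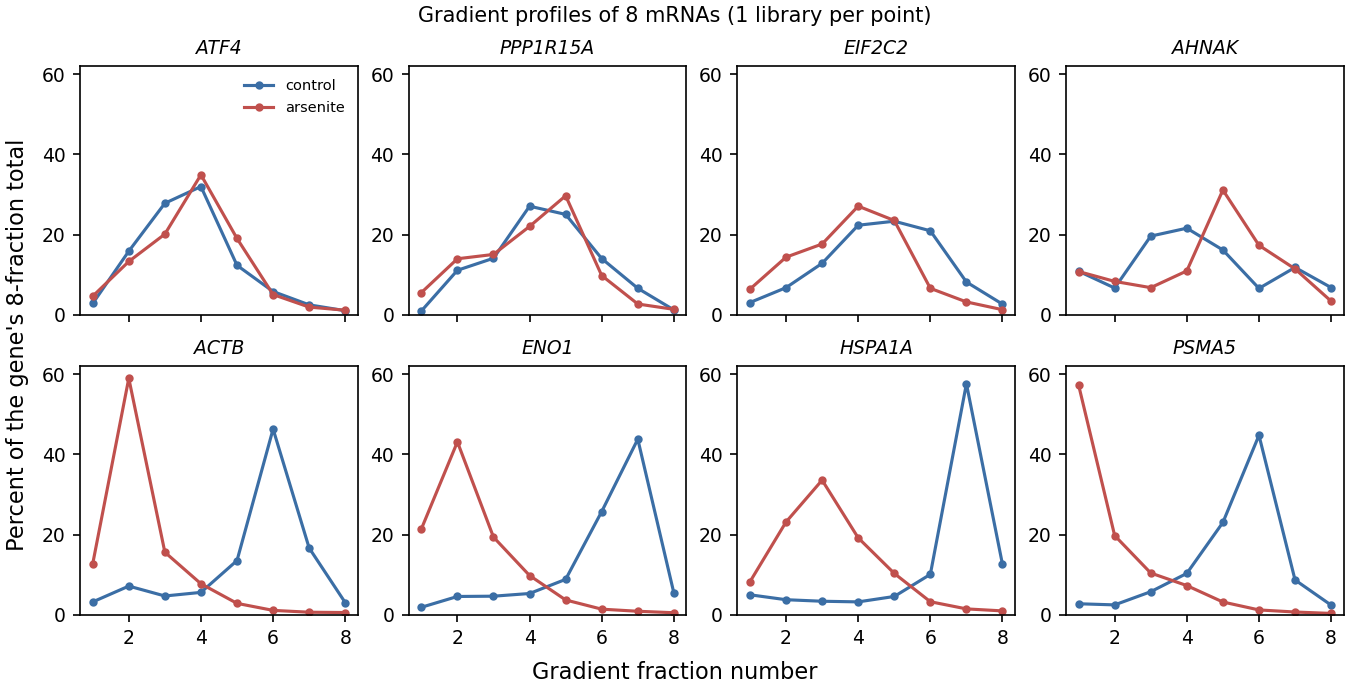
Share of each gene's 8-fraction total (y axis, percent) against gradient fraction number (x axis) for 8 mRNAs in control and arsenite gradients, with 1 library per point. ATF4 and PPP1R15A have similar profiles in both gradients, and ACTB goes from a peak of 46.3% in fraction 6 to one of 59.0% in fraction 2.

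The genes with the largest relative shifts to higher numbers had values of 0 in several libraries. They were C14orf38, SLC6A13, SLC15A2, TF, SYT12, TTN, ITGB1BP2, ABCA13, CELF6 and PARP14, with relative shifts from 5.06 for C14orf38 to 2.73 for PARP14 (1.82 with size factors), and each was listed at 0 in 3 to 10 of the 16 libraries. In every case arsenite fraction 3, the library of that gradient with the most genes at 0, was among these. C14orf38 did not meet the rule without fraction 5 or 6. Among genes with no 0, a restriction added after the values were seen, the largest were UNC5CL (2.17), WDR52 (2.09), the myosin gene MYH3 (1.95, but 0.75 with size factors), AGAP6 (1.90), CCDC80 (1.89), LRRC39 (1.86), SHANK2 (1.85), AKAP12 (1.82), FMN1 (1.78) and AHNAK (1.77). The 10 largest to lower numbers were ACTL8, NUP37, BCKDHA, EDARADD, TUBA1A, HIST1H1A, ENO1, HNRNPCL1, SCAND1 and PIR, from −2.31 for ACTL8 (−3.53 with size factors) to −2.03 for PIR. ACTL8, HNRNPCL1 and SCAND1 were listed at 0 in 6, 2 and 3 libraries. BCKDHA, a subunit of the enzyme that breaks down branched-chain keto acids, had 86.4% of its total in fractions 5 to 8 in the control and 5.67% with arsenite. Without ACTL8, HNRNPCL1 and SCAND1, the next genes with no 0 were PKM (−2.00), PSMA5 (−1.97) and CCT8 (−1.96).

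Of the fixed gene lists, 16 had at least 2 measured members, and 11 of these stood apart, meaning that the median relative shift lay outside the central 95% of 10000 random lists of the same size. Glycolysis lay lowest, with a median relative shift of −1.59, and all 16 measured members moved lower. PKM, which makes pyruvate, lay at 6.20 in the control and 2.74 with arsenite, LDHA at 5.63 and 2.42, and GAPDH had a relative shift of −1.23. Of 30 proteasome subunits, 29 moved lower, and the median was −1.42 (−2.06 with size factors). PSMA5 lay at 5.29 and 1.87 and PSMB3 at 5.31 and 1.94 (relative shift −1.92, and −2.95 with size factors), while PSMC6, at −0.09 (0.20 with size factors), did not meet the rule. Among 75 nuclear-encoded subunits of oxidative phosphorylation, 58 moved lower, none moved higher and 17 met neither rule, and the median was −1.18 (−1.90 with size factors). ATP5H went from 4.84 to 1.47 and ATP5B from 5.54 to 2.28, both parts of ATP synthase.

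Cell cycle mRNAs had a median relative shift of −1.02, and 22 of 27 moved lower. CCNB1, the mitotic cyclin B1, lay at 5.46 in the control and 2.34 with arsenite, CDC20 at 5.37 and 2.26, and MCM5, a subunit of the replicative helicase, at 6.01 and 2.90. CCND1, cyclin D1, had a relative shift of −0.02, which was 0.07 with size factors. Replication-dependent histones, whose mRNAs end in a stem-loop in place of a poly(A) tail, had a median of −0.94 (−1.66 with size factors), with 41 of 50 moved lower. HIST1H1A lay at 5.20 and 1.61. Histone genes are close copies of each other, so reads could be split between them, and single members are uncertain. The histone list had a median annotated mRNA length of 436.5 nt. It no longer stood apart from random lists matched on control position and mRNA length, a comparison added after the data were seen, whereas the cell cycle, glycolysis, proteasome and oxidative phosphorylation lists did. Against lists matched on mRNA length alone all 5 stood apart, though the shortest length bin, from 177 to 1406 nt, reached far above the histone median.

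Among 26 early stress transcripts, 12 moved lower and none moved higher. HSPA1B and HSPA1A, the inducible HSP70 genes, had relative shifts of −1.61 and −1.56. HSPD1, the mitochondrial chaperonin, had one of −1.43, and HMOX1, heme oxygenase 1, one of −0.99. HSPA1A and HSPA1B are nearly identical, so their values are uncertain, and they no longer met the rule without fraction 7 (−0.80 and −0.97) or fraction 8 (−1.41 and −1.42), as their sign then turned with a further fraction left out. The transcription factors FOS (0.13, and 0.23 with size factors) and ATF3 (−0.11, and again 0.23) did not meet it. The list's median was −0.36. It stood apart in the main comparison, but neither without fraction 6 (−0.29), nor over genes with no 0 (−0.33), nor against lists matched on control position or on mRNA length. With size factors the median was again −0.36 but did not stand apart, as the central 95% of random lists, from −0.35 to 0.33 in the main comparison, then ran from −0.49 to 0.46. For 20 chaperones and unfolded protein response genes of the endoplasmic reticulum the median was −0.67, with 12 moved lower and 1 higher. CALR, calreticulin, lay at 5.37 in the control and 2.56 with arsenite and PDIA4 at 5.35 and 2.77, and EDEM1 was the member that moved higher (0.91). HSPA5 had a relative shift of −0.33, which was −1.06 with size factors and −0.89 without fraction 5. Without fraction 7 this list lay at −0.38 and no longer stood apart, nor did it against lists matched on control position and mRNA length. Stress granule proteins had a median of −0.26 and did not stand apart, with 9 of 24 moved lower and 1 higher. G3BP1 (−1.37) and G3BP2 (−1.16), which nucleate these granules, moved lower, PUM2 moved higher (0.91, and 1.58 with size factors), and TIAL1 had a relative shift of 0.05 (0.03). Without fraction 1 or 5 the list lay at −0.41 and −0.44 and stood apart, as it did lower than lists matched on mRNA length.

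Messenger RNAs of the translation machinery did not stand apart as lists in the main comparison. Among 75 cytosolic ribosomal proteins 8 moved higher, 11 moved lower and 56 met neither rule, and the median relative shift was −0.16. Their median position was 3.91 in the control and 2.24 with arsenite. RPS7 lay at 4.93 and 1.68 (−1.79, and −2.91 with size factors), though without fraction 1 its relative shift was −0.41, whereas RPS3A, at 2.78 and 2.58, moved higher (1.25). The placing of this list turned on single fractions, since its median was 0.28 without fraction 1 and −0.57 without fraction 3, and stood apart in each case. With size factors it was −0.45 and stood apart. It lay 0.56 fractions below the middle of lists matched on control position and 0.30 above that of lists matched on mRNA length, apart in each case, and did not stand apart from lists matched on both. Of 21 translation factors and other mRNAs with a 5 prime terminal oligopyrimidine tract, 2 moved higher and 5 lower, with a median of −0.18 (−0.43 with size factors). BTF3 lay at 4.44 and 1.82 (−1.16, and −0.38 without fraction 1), and EEF1A1, the most familiar member, lay at 4.77 and 3.71.

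In the main comparison 4 lists stood apart at higher fraction numbers than random lists. In the list of 15 mRNAs with upstream reading frames known for translation when eIF2 is phosphorylated, 7 moved higher and 2 lower, with a median of 0.45. Besides ATF4 and PPP1R15A these were PCNXL4 (0.82, and 1.46 with size factors), DDIT3 (0.79), ATF5 (0.75), IFRD1 (0.74) and PPP1R15B (0.68). DDIT3 and ATF5 are further transcription factors of the stress response. EPRS, a tRNA synthetase (−0.93, and −1.65 with size factors), and UCP2, a mitochondrial carrier (−0.63, and −0.38 without fraction 5), moved lower. IFRD1 lay at 0.47 with size factors, under the threshold. The list's median lay just past the random lists, at percentile 98.0, and no longer stood apart with size factors (0.58), without fraction 6, 7 or 8 (0.31, 0.36 and 0.40), or against lists matched on control position.

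Argonaute and silencing genes had a median relative shift of 0.60, and 13 of 22 moved higher. All 4 Argonaute genes were among them, from EIF2C4 (1.16) and EIF2C1 (0.85) to EIF2C3 (0.76, and 1.13 with size factors) and EIF2C2 (0.67), as was TNRC6A (0.91), which encodes a GW182 partner of Argonaute. XPO5, which exports microRNA precursors from the nucleus, was the 1 that moved lower (−0.97, and −0.47 without fraction 7). The Argonaute and silencing list had a median annotated mRNA length of 7014.5 nt. Among the 1303 longest mRNAs, from 7394 nt, the median relative shift was 0.45 and 586 moved higher. The list lay 0.28 above the middle of lists matched on control position and mRNA length, against 0.61 without matching. It still stood apart from the matched lists, but narrowly, as the upper end of their central range was 0.57. Of 39 mRNAs with very long coding sequences, 20 moved higher and none lower, with a median of 0.53. AHNAK lay at 4.26 in the control and 4.58 with arsenite, MACF1 at 4.61 and 4.75, and PKD1 at 4.13 and 4.26. With size factors the median of the very long list was −0.12, the opposite direction, and without fraction 5 or 6 it was 0.11 and 0.24 and did not stand apart. Nor did it stand apart from lists matched on mRNA length alone. It did stand apart from lists matched on control position, 1.03 above their middle, and on control position and mRNA length, 0.32 above. Among 437 zinc finger genes named ZNF, 245 moved higher and 5 lower, with a median of 0.56. ZNF418 lay at 3.56 and 4.02 and ZNF471 at 3.71 and 4.70, although they were listed at 0 in 4 and 7 libraries. ZNF622 lay at 5.76 and 2.93 and moved lower. Reads can be shared between related zinc finger genes.

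**Figure D3:**
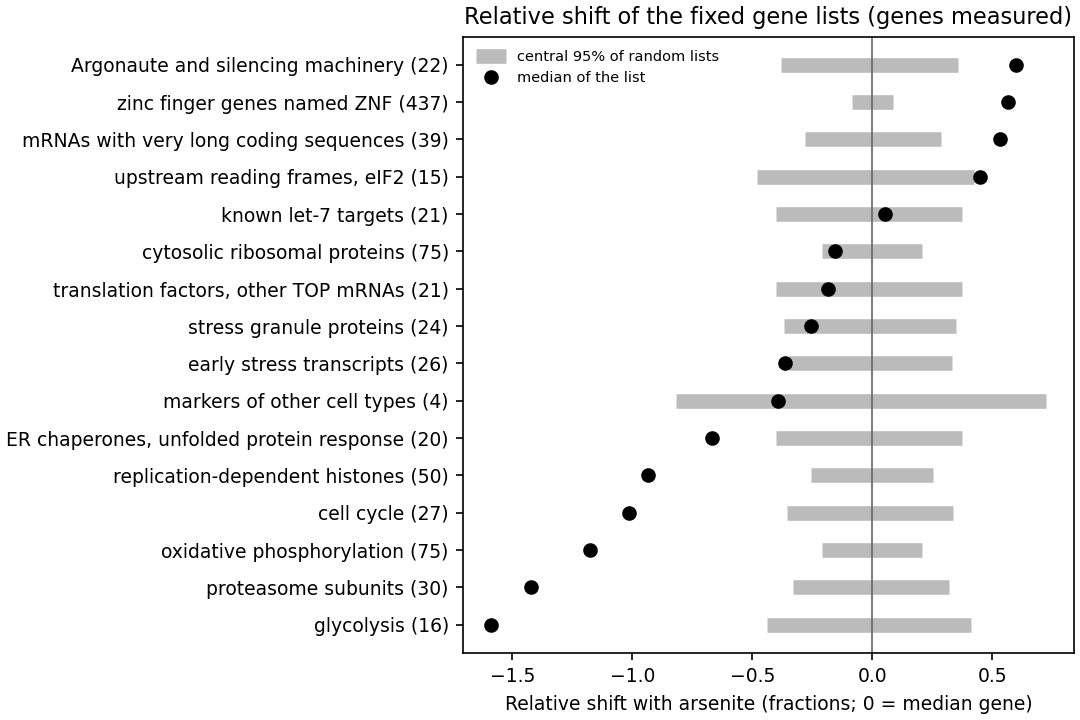
Median relative shift with arsenite (x axis, fractions, where 0 is the median gene) of each fixed gene list (y axis, number of genes measured in parentheses). Black points are list medians and grey bars the central 95% of 10000 random lists of the same size. Glycolysis lies at −1.59 and Argonaute and silencing machinery at 0.60, and the list of very long coding sequences, here at 0.53, lies at −0.12 with size factors.

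Known targets of the let-7 microRNA did not stand apart, with a median relative shift of 0.05 over 21 genes (0.13 with size factors), 6 of them moved higher and 4 lower. NR6A1 (1.24) and LIN28B (1.15) moved higher, and HMGA2, a classic target, had a relative shift of 0.05 (0.22 with size factors). Of 21 markers of other cell types, 4 were in the table. These were the actin gene ACTA1 (0.85), the collagens COL3A1 (−0.18, and −1.26 with size factors) and COL1A1 (−0.73, and −0.25 without fraction 7), and the globin HBA1 (−0.61, but 0.69 without fraction 1 and −1.77 with size factors). Their median was −0.39 and did not stand apart, though it did with size factors (−1.16). TAF1D was the 1 measured member of the list meant for noncoding hosts of small nucleolar RNAs, though it has a protein-coding transcript in the annotation. It lay at 3.72 in the control and 3.17 with arsenite.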

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

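The alternatives of genes with no 0 and of matched random lists were chosen after seeing the data. With median-of-ratios size factors the median shift with arsenite was −0.23 and the median difference in the share in fractions 5 to 8 was −2.82 percentage points, against −1.46 and −33.5. Such factors set the typical gene alike in all libraries by construction, so they remove any shift common to most genes. The matched log2 medians of fractions 2 and 7 became −0.076 and −0.058, those of fractions 3, 5 and 6 became −0.044, 0.11 and 0.12, and the list of very long coding sequences lay at −0.12. Of the 6260 genes called moved, 5424 were also called with size factors, all in the same direction, and relative shifts correlated at 0.93 across genes (Spearman). Adding 1 percentage point before shares were taken gave a median shift of −1.35 and a share difference of −31.0, and the point at which 50% of the total is reached gave a shift of −1.82; the cause was not tested. Leaving out each fraction gave control positions from 4.23 to 4.81, shifts from −1.70 to −1.21 and share differences from −41.5 to −27.2. It gave 2712 to 3459 genes moved higher, 2559 to 3358 moved lower, and 8 to 13 lists that stood apart, the lowest without fraction 6. A threshold of 1 fraction gave 879 genes moved higher and 1227 lower, fewer by construction. Pseudocounts of 0.1 and 10 gave log2 medians of 1.62 and 0.91 in fraction 2 and −2.44 and −0.63 in fraction 7. Against random lists matched on control position and mRNA length, 7 lists stood apart in place of 11, and the early stress list lay 0.072 above their middle. The ribosomal protein list reversed and stood apart higher without fraction 1 (0.28) and without fraction 5 (0.22), in a range from −0.57 to 0.28 when each fraction was left out, and it lay 0.30 above the middle of lists matched on mRNA length. HBA1 ranged from −0.88 to 0.69 in the same way. Over all list values under the alternatives, 213 kept their direction and call, 18 lost the call, 9 gained it and 5 reversed, and 11 that stood apart in neither case changed sign. Filters on low values, summed abundance and a choice among several rows per gene were not run, because shares carry no level and each gene has 1 row. No paired analysis was possible because the result comes from no test and each group has 1 library. Unknown depth limits what can be said of genes with values of 0.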

Other observations

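Gene families defined by the stem of their symbols were examined after the main results were seen, against random lists matched on control position and mRNA length. Of 159 families with at least 10 members, 19 lay lower and 11 higher than the central 95% of matched lists, where chance would give 7.95 in all. Some repeated the fixed lists, and of the 131 families with no member in one, 12 lay lower and 10 higher, where chance would give 6.55. With size factors, 13 of the 19 and 7 of the 11 stood apart in the same direction. Mitochondrial ribosomal proteins lay lower, with 40 of 47 MRPL genes and 26 of 29 MRPS genes moved lower and none higher. The MRPL family had a median position of 4.56 in the control and 1.98 with arsenite, and the MRPS family 4.59 and 2.17. The HSPA chaperones (8 of 11 moved lower), annexins (ANXA, 9 of 10) and aldehyde dehydrogenases (ALDH, 12 of 16) did the same, with median relative shifts of −1.24, −1.48 and −1.14. Of the HSPA members, 4 were also in a fixed list. Among the 11 families that lay higher were ZBTB (20 of 38 moved higher, none lower), HOXA (8 of 11, none lower) and ANKRD (22 of 40, 1 lower), with medians of 0.53, 0.66 (1.11 with size factors) and 0.58. MTRNR2L1 and MTRNR2L8 are nuclear genes that resemble the mitochondrial ribosomal RNA. In the deposited shares they hardly changed place, at 2.57 and 2.49 in the control and 2.63 and 2.53 with arsenite.

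The length of an mRNA went with its position far more closely after arsenite than before. Across 13030 genes, which are not independent replicates, the Spearman correlation of annotated mRNA length with position was 0.23 in the control and 0.67 with arsenite. The value with arsenite was 0.70 over genes with no 0, and 0.68 with size factors. The control value was not recomputed in these ways, so they do not check the contrast. For coding length the correlations were 0.38 and 0.67. The 1303 shortest mRNAs, up to 1406 nt, had median positions of 4.25 and 2.10, and the 1303 longest, from 7394 nt, of 4.77 and 3.78. Among the shortest, 127 genes moved higher and 641 lower, and among the longest 586 and 76. Of genes with 0, 1 and 2 or more start codons in the annotated 5 prime UTR, 15.9%, 24.9% and 32.4% moved higher. Of the genes moved higher 79.0% had no value of 0, against 88.4% of all genes and 93.4% of those moved lower.

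Among the tests below, those of how the fractions were weighted, of the starting position in the control, of the length of the mRNA alone and of 3 lists taken apart were chosen only after the result was seen, and the matching on control position and mRNA length was chosen after the data were seen, though before its own result. Of the genes that moved to higher fraction numbers, 86.8% also moved higher with size factors, so most of these calls did not turn on the choice between these 2 weightings. The threshold of 0.5 fractions was easier to meet with size factors, because relative shifts were more spread out. No other weighting was tried, so how the fractions were weighted stays open as a cause. Whether the length of the mRNA alone suffices stays open: 70.7% of these genes stayed at least 0.5 fractions above genes of the same length, but 955 of the 3058 with a known length lay in length bins with a median below 0 and so stayed by construction. Above genes of the same control position 54.3% stayed (56.6% with 5 bins in place of 20), and above genes of the same control position and length 33.0%, so the 2 together may account for most of the pattern, though the control position is itself part of the shift. The Argonaute, very long coding and ZNF lists still stood apart higher than lists matched on both, at 0.28, 0.32 and 0.29 fractions above their middle. The list with upstream reading frames did not. The very long list had a median length of 14437 nt, in a length bin from 7394 to 101518 nt with a median of 9427. The matching on both therefore cannot remove length for the very long list. That list did not stand apart from lists matched on length alone, and with size factors its median was −0.12. Genes with 2 or more upstream start codons lay 0.080 fractions above lists matched on control position (3 bins), mRNA length (5 bins) and 5 prime UTR length (5 bins). A contribution of upstream reading frames, small against the 0.5 fractions of the rule, is possible. Differences left within such wide bins could also give a small excess, so the matching cannot tell these apart. With 1 gradient per treatment, a difference between the gradients themselves stays open.

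The second pattern is the 7 lists that stood apart lower than random lists. With size factors 6 of the 7 still stood apart lower, which argues against the choice between the deposited weighting and size factors as their cause. Among these 6, the endoplasmic reticulum list lay at −0.38 without fraction 7 and no longer stood apart, so for it weighting stays open. No other weighting was tried. The starting position in the control alone is argued against for 6 of the 7, which lay below lists matched on it. Against lists matched on the length of the mRNA alone 6 of the 7 also lay lower, which argues against length except for the histones. The histones had a median length of 436.5 nt, in a length bin from 177 to 1406 nt with a median of 1062. This matching cannot remove length for them. The list that stood apart in none of these was early stress. It lay 0.15 below the middle of lists matched on position and 0.18 below that of lists matched on length. With size factors its median was again −0.36, but relative shifts were more spread out over all genes and it no longer stood apart. Weighting therefore stays open as a cause for this list. Against lists matched on the starting position in the control together with length of the mRNA, 4 of the 7 still stood apart lower. These were oxidative phosphorylation, proteasome, cell cycle and glycolysis, at −0.53, −0.43, −0.35 and −0.77 fractions from the middle of those lists. This argues against the 2 together for oxidative phosphorylation, which started near the median gene (4.46 against 4.54). The other 3 started at 5.17, 5.31 and 5.74, above the upper quartile of 4.96. Differences left within the 5 wide position bins could add to their distances, so for them the 2 together stay open. The early stress, histone and endoplasmic reticulum lists were taken apart after they had lost the call in this matching, so the count of 0 of the 3 still below lists matched on both adds no support. They lay at 0.072, −0.025 and −0.12 fractions from the middle of those lists. At these distances the starting position in the control together with length of the mRNA may account for their place. Random lists could not be matched on expression, because shares carry no level, so a link with expression level or read depth was not examined. A biological effect of arsenite on the oxidative phosphorylation, proteasome, cell cycle and glycolysis lists stays a hypothesis, untested without a replicate.

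The third concerns sites for 8 microRNA families in annotated 3 prime UTRs, a hypothesis drawn from the subject of the series. Genes with a site were set against lists matched on control position and 3 prime UTR length and against shuffled sites of the same bases. Outside both controls in 1 direction lay 2 of the 8 families, miR-92 and miR-19, both higher, by 0.07 and 0.06 fractions. At least 4 families had been set beforehand as a sign that sites of 8 microRNA families go with the shift, and at most 1 as a sign that they do not, so the number found keeps the question open. Genes with a let-7 site lay inside the central 95% of both controls.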
